A study of Mus musculus with 8 samples.

How the data were processed

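RNA sequencing was used to measure gene expression in C57BL/6 mice that were wild-type (WT) or carried a loss of Hdac3 (KO). One set of libraries came from neurospheres, floating cultures of neural stem and progenitor cells, grown for 4 days from cerebrum taken at embryonic day 16.5. The other set came from the dorsal cerebral cortex at postnatal day 0. The design text of the series lists 2 WT and 2 KO brains for each tissue, which gives 8 libraries in 4 groups, so replicates were read as separate brains. The titles of the cortex KO samples name Emx1 and the authors' deposited cortex table names a Cre driver of that gene, which acts in progenitors of the dorsal telencephalon and their descendants. Cells of other origin in the tissue, such as microglia and interneurons born ventrally, need not lack the enzyme. The driver used for neurospheres was not given in the sources used here. The libraries are named by the numbers in the labels: WT 5, WT 6, KO 7 and KO 8 for neurospheres, and WT 1, WT 2, KO 1 and KO 2 for cortex. The submitters described the library kit as stranded and primed from poly(A) tails.

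Per the submitters' processing notes, the authors used Trim Galore, STAR, featureCounts, DESeq2, Bowtie and Cufflinks with the mouse build mm9, each with its version not given in the sources used here. The authors deposited FPKM values (fragments normalized to transcript length and to the number of mapped fragments) from 1 Cufflinks run per library, with the bounds of the confidence interval of each value. The same deposited tables gave the ratio of KO to WT FPKM, which the authors computed as the mean of the ratios of the libraries paired in column order. These ratios were not used as a test. A second pair of deposited tables held a signal column (the mean normalized count over the libraries), the log2 fold change, its standard error and the p-value with its adjusted value, which the authors computed with DESeq2 and which appear here only as the authors' values. These fold changes appear to be pulled toward 0 where libraries differ. In cortex Ddx3y had −0.02 (SE 0.05) there, with FPKM of 10.83 and 10.86 in WT and 0 and 8.13 in KO. Their sizes are thus not directly comparable with the FPKM fold changes. The remaining pair gave the authors' gene ontology term enrichment, with a p-value and an odds ratio per term, for which the tool and input genes were not given in the sources used here. How strand was used in counting was not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. The supplied reference annotation used another build than mm9, so it served only to check gene symbols and no coordinates were printed. It held 96.5% of the neurosphere symbols and 96.4% of the cortex symbols.

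The neurosphere FPKM table held 11536 rows and that of cortex 12106. No WT value was below 0.99 FPKM, whereas KO values below 0.99 occurred in 677 neurosphere rows and 359 cortex rows. The tables had therefore been restricted on the WT libraries, and a gene silent in WT that came on in KO was outside these fits. Rows with a calendar date in place of a symbol (20 and 21) were removed. Repeated symbols (20 and 29) were reduced to the row with the highest mean FPKM, which left 11496 and 12056 genes. In neurospheres 85 genes were listed at 0 in at least 1 library and 16 in both KO libraries. In cortex these numbers were 22 and 7. No WT library held such a gene.

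Total counts per library were not used here. The width of the Cufflinks intervals, read as 2 standard deviations on each side, implied 9500000, 9500000, 8500000 and 9300000 fragments in WT 5, WT 6, KO 7 and KO 8, and 14000000, 14500000, 18200000 and 16200000 in cortex WT 1, WT 2, KO 1 and KO 2. The median gene then rested on 346 to 440 fragments in neurospheres and 580 to 709 in cortex. The Pearson correlation of log2(FPKM + 1) across genes between replicates was 0.976 for WT and 0.967 for KO neurospheres, and 0.996 and 0.995 for cortex. Genes are not independent replicates in such a correlation.

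The analysis was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with a mean of at least 1 FPKM were kept, a pseudocount of 1 was added and values were taken to log2. Each tissue was fitted separately with limma-trend (the limma empirical Bayes test with a mean-variance trend, two-sided), with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. The difference of the KO effect between tissues was tested with limma-trend on all 8 libraries, as a contrast of differences taken within each table, for genes kept in both. Overlap of calls was tested with the one-sided Fisher exact test, with BH over the 4 pairings of directions. Lists of genes were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation, with BH over lists with at least 4 measured members. The preset value can lie below the real correlation and give p-values that are too small. With an estimated correlation the test rests on the few residual degrees of freedom of the libraries, so few lists can pass. A miss there cannot decide whether correlation between genes accounts for a shift. Of 43 lists of cell type markers, pathways and complexes, 32 were tested in neurospheres and 39 in cortex. Fold changes are those of log2(FPKM + 1) unless a ratio of mean FPKM is named. Permutation tests shuffled genes, with 100000 resamples. Genes are not independent replicates, so these p-values do not measure the spread between libraries.

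The tests, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took Hdac3, the 8 genes with the largest rise and the 8 with the largest fall in each tissue among those past the threshold with both KO libraries on one side of both WT libraries, up to 4 members of each list by adjusted p, the 5 largest differences between tissues in each direction, and 5 genes per direction of the overlap. Predicted gene models, microRNA and small nucleolar RNA genes were counted but not named, and some members of the lists are not reported here. Where a gene was listed at 0 no fold change is given, and the next genes by the same order were named in its place, a choice made after the values were seen. The alternatives were another pseudocount, other filters, median-ratio rescaling and quantile normalization of the libraries, each library left out, a spread estimated over all 8 libraries, robust moderation, a fold change minimum, a replicate block in cortex, and the authors' own calls.

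The procedure was tested on simulated data with the same numbers of libraries, in which 200 of the more highly expressed genes had been changed. The noise was normal and independent between genes, with the moderated spread of the fit, so recovery in the real data can be lower. For a log2 change of 1 the procedure recovered 87% of the changed genes in neurospheres, 100% in cortex and 72% in the difference between tissues. For a log2 change of 2 it recovered 100% in each, with 15, 15 and 7 false calls. With 2 libraries per group neither a test for outlying libraries nor a count of other splits of the samples was run.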

Results

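Expression was measured in 8 RNA-seq libraries, 2 WT and 2 Hdac3 KO libraries each from cultured neurospheres and from newborn cortex. Hdac3 encodes a class I histone deacetylase, the catalytic subunit of the NCoR and SMRT corepressor complexes. The design asked which genes changed in KO neural progenitor cultures and in KO cortical tissue, and whether the same genes changed in both. Depth implied by the deposited intervals was 8500000 to 9500000 fragments per neurosphere library and 14000000 to 18200000 per cortex library. Values below are FPKM as mean ± SD with n = 2 per group unless stated otherwise.

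Hdac3 itself was lower in the KO libraries of both tissues. In cortex its level was 47.1 ± 1.41 FPKM in WT (48.1 and 46.1) and 27.0 ± 0.23 in KO (26.8 and 27.1), a ratio of 0.572. The log2 fold change was −0.78 (adjusted p = 0.000319, limma-trend with BH). In neurospheres Hdac3 measured 31.5 ± 4.06 FPKM in WT (34.4 and 28.7) and 19.3 ± 1.73 in KO (18.0 and 20.5). There the log2 fold change of −0.68 missed the threshold (adjusted p = 0.104, limma-trend with BH). The authors' deposited table gave −0.52 for cortex (adjusted p = 3.83e-07) and −0.29 for neurospheres (adjusted p = 0.437). FPKM is a value for the whole gene and does not resolve the deleted part of the transcript.

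**Figure D1:**
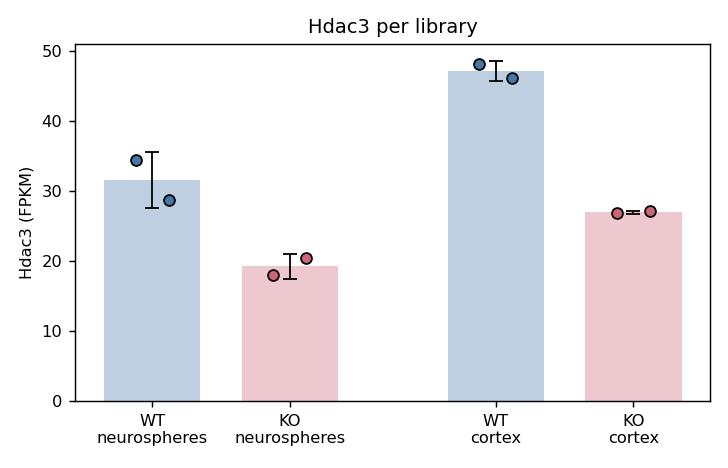
FPKM of Hdac3 in each of the 8 libraries, with points for libraries and bars for group means. The cortex KO libraries lie at 26.8 and 27.1 FPKM against 48.1 and 46.1 in WT, and the neurosphere KO libraries at 18.0 and 20.5 against 34.4 and 28.7.

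In KO neurospheres 8 of 18 measured GABAergic interneuron genes rose and 9 of 11 hypoxia response genes fell, and neither list passed with an estimated correlation (adjusted p = 0.582 for each). Few lists can pass that test with 2 libraries per group. The largest rise was in Spp1, which encodes the secreted phosphoprotein osteopontin. It went from 3.95 ± 1.29 FPKM in WT to 146 ± 38.4 in KO, a ratio of 37.0. The metallothioneins Mt2 and Mt1, which bind zinc and copper, fell from 163 ± 42.7 to 15.5 ± 4.13 and from 237 ± 50.1 to 34.6 ± 21.4 FPKM. Of 11408 genes tested with limma-trend and BH, 25 were higher and 106 lower in KO.

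The other genes with the largest rises included chains of collagen IV, the main collagen of basement membranes. Col4a1 rose from 3.08 ± 0.00207 to 17.3 ± 2.30 FPKM (log2 fold change 2.16, SE 0.19, adjusted p = 0.00972), and Col4a2 from 4.38 ± 0.908 to 18.3 ± 1.42 (log2 fold change 1.85, adjusted p = 0.0176). Dcn, the small proteoglycan decorin, rose by a log2 fold change of 1.74 (adjusted p = 0.0358). Neat1, the long noncoding RNA that scaffolds nuclear paraspeckles, rose from 3.32 ± 0.559 to 13.4 ± 3.70 FPKM (adjusted p = 0.0354). Rasgef1b, a guanine nucleotide exchange factor for Ras proteins, rose by 1.57 on the log2 scale (adjusted p = 0.0358). The alpha globin gene Hba-a1 rose by 1.56 (adjusted p = 0.0471), with an uncertain share of its reads from its near-identical copy. Dlx6, a homeobox gene of forebrain GABAergic neurons, rose from 3.43 ± 0.693 to 9.55 ± 0.0823 FPKM (adjusted p = 0.0471), and its overlap with the antisense transcript Dlx6os1 leaves the value uncertain.

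Among the genes with the largest falls Slc16a3, a lactate exporter, went from 5.70 ± 0.059 to 0.042 ± 0.0172 FPKM (log2 fold change −2.69, adjusted p = 0.00972). Bnip3, a hypoxia-induced mitochondrial protein, fell from 25.2 ± 0.0426 to 5.17 ± 0.592 FPKM (log2 fold change −2.09, adjusted p = 0.00889), and Fam162a from 41.5 ± 3.93 to 8.50 ± 4.68 (adjusted p = 0.0354). Id1, an inhibitor of basic helix-loop-helix transcription factors, fell from 19.4 ± 7.32 to 4.00 ± 1.61 FPKM (adjusted p = 0.0423). Dio2, the deiodinase that activates thyroid hormone, fell from 7.45 ± 0.624 to 1.19 ± 0.413 FPKM (adjusted p = 0.0266), and Nwd2 from 7.68 ± 2.32 to 1.22 ± 0.756 (adjusted p = 0.0447). Taf10 and Cox4i2 were listed at 0 in both KO libraries, against 23.5 and 17.3 FPKM and 4.51 and 3.03 FPKM in WT. The authors' deposited table gave Taf10 a log2 fold change of −0.22 (adjusted p = 0.763).

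Of 18 measured genes of GABAergic interneurons, 8 rose and 10 did not pass, 13 rose when adjusted over the list alone and 12 after rescaling, and all 18 were above 0. Dlx2, a homeobox factor of the ganglionic eminences, rose from 11.2 ± 0.00997 to 27.9 ± 2.43 FPKM (adjusted p = 0.0282), Maf from 16.7 ± 0.944 to 37.8 ± 1.36 (adjusted p = 0.0309) and Lhx6 from 29.1 ± 1.16 to 62.3 ± 0.929 (adjusted p = 0.0309). Dlx1 rose by 1.09 on the log2 scale (adjusted p = 0.0347). The list had a median log2 fold change of 1.02 and a camera adjusted p of 1.23e-23, against adjusted p = 0.582 with an estimated correlation. The authors' deposited table called 13 of 20 members higher. Of 11 genes of the hypoxia response 9 fell, and 11 fell adjusted over the list alone. The glucose transporter Slc2a1 fell from 26 ± 1.88 to 6.04 ± 0.654 FPKM (adjusted p = 0.00972), lactate dehydrogenase Ldha from 259 ± 53.3 to 77.9 ± 0.950 (adjusted p = 0.0196), and the oxygen sensor Egln3 from 8.55 ± 0.802 to 1.52 ± 0.284 (adjusted p = 0.0233). The list median was −1.70, or −1.62 without Car9, which was listed at 0 in both KO libraries (camera adjusted p = 1.96e-13, and adjusted p = 0.582 with an estimated correlation).

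Of 20 genes of the G2 and M phases, 2 fell, 16 fell adjusted over the list alone, and none passed after rescaling of the libraries (camera adjusted p = 1.73e-09, and adjusted p = 0.604 with an estimated correlation). Tpx2, a spindle assembly factor, went from 24.9 ± 0.570 to 11.9 ± 0.505 FPKM (adjusted p = 0.0401) and cyclin B1 (Ccnb1) from 13.2 ± 0.859 to 5.55 ± 0.0951 (adjusted p = 0.0433). Their rescaled adjusted p values were 0.0543 and 0.0531. Of 18 S phase genes 0 passed at the threshold of limma-trend, 4 fell adjusted over the list alone, and the median was −0.46 (camera adjusted p = 0.00384, and adjusted p = 0.688 with an estimated correlation). Of 22 radial glia genes only the glutamate transporter Slc1a3 fell, from 199 ± 5.64 to 76.1 ± 1.32 FPKM (adjusted p = 0.0181). Adjusted over the list alone 1 rose and 6 fell, and after rescaling 1 and 1 (camera adjusted p = 0.139). Of 12 astrocyte genes 2 fell, or 3 adjusted over the list alone. These were Sparcl1, a secreted matrix protein, from 91.7 ± 6.62 to 31.2 ± 3.21 FPKM (adjusted p = 0.0147), and Id3, from 35.3 ± 6.46 to 11.2 ± 1.32 (adjusted p = 0.0239). The astrocyte list gave a camera adjusted p of 0.0209, and adjusted p = 0.629 with an estimated correlation.

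Of 11 extracellular matrix genes Col4a1 and Col4a2 rose and the proteoglycan Bcan fell from 42.4 ± 2.00 to 19.1 ± 3.75 FPKM (adjusted p = 0.0421), with 3 higher and 1 lower adjusted over the list alone. The camera adjusted p was 0.00166, and adjusted p = 0.629 with an estimated correlation. The authors' deposited table called 9 of 17 members of this list higher and 1 lower. Those higher included Col6a1, Col6a2 and Col6a3 (log2 fold changes of 2.55, 3.23 and 3.74 there). These 3 genes were absent from the FPKM table and thus from the 11 genes fitted here. Of 18 pan-neuronal genes 0 passed at the threshold of limma-trend and 7 were higher adjusted over the list alone, and 1 after rescaling. Neurod2 had a log2 fold change of 0.65 (adjusted p = 0.1). The list median was 0.22 (camera adjusted p = 0.000139, and adjusted p = 0.629 with an estimated correlation). Of 20 ribosomal protein genes 0 passed, also adjusted over the list alone, and the median was −0.52, or −0.36 after rescaling (camera adjusted p = 0.000193, and adjusted p = 0.719 with an estimated correlation). Of the other lists, 4 of the 12 past the camera threshold are given with the closing observations.

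**Figure D2:**
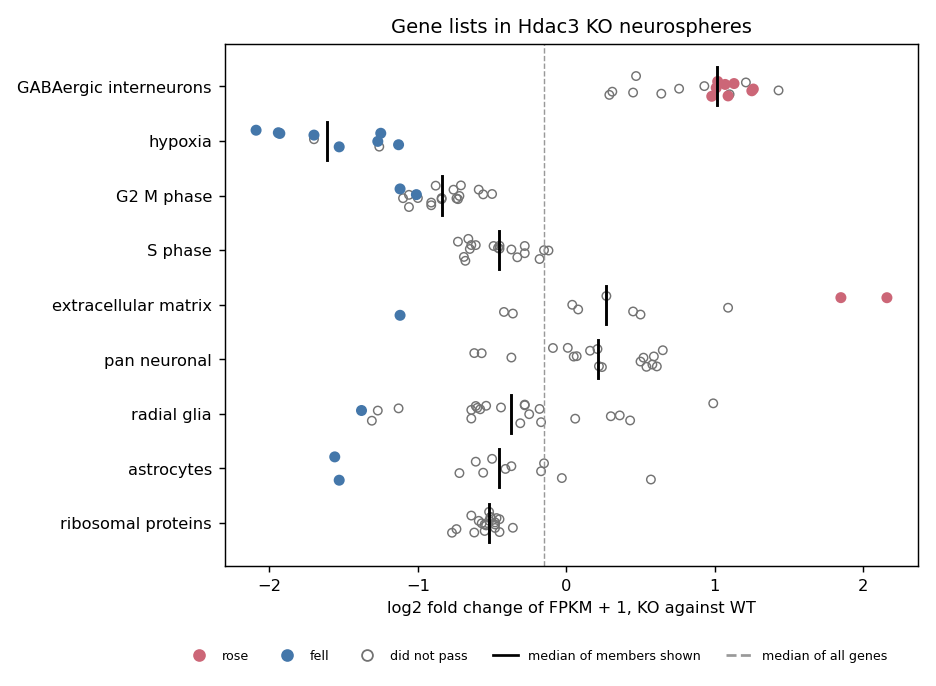
Log2 fold change (KO against WT) of each measured member of 9 gene lists in neurospheres, with filled points for genes past the limma-trend threshold, a black bar for the median of the members shown and a dashed line for the median of all genes (−0.15). Members listed at 0 are not drawn. All 18 interneuron genes lie above 0 and the hypoxia genes shown lie between −2.09 and −1.13.

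More genes were lower than higher in KO neurospheres under each scaling. The FPKM table was restricted on WT, which leaves out genes that came on only in KO and can favour falls. The median log2 fold change of all genes was −0.15, and 52 genes were higher and 78 lower after median-ratio rescaling, and 71 and 88 after quantile normalization. The authors' deposited table, which rests on other counts, another test and another set of genes, called 437 higher and 288 lower. Of these, 70 and 15 were outside the FPKM fit, so the authors called more genes higher than lower also among the genes fitted here. The count was 1668 with the spread estimated over all 8 libraries and 65 with a pseudocount of 0.1, where Dcn, Hba-a1, Dlx6, Fam162a, Id1, Nwd2, Bcan and Ccnb1 missed the threshold, and limma-trend with BH called 0 genes without WT 5 or without WT 6 (1227 and 2672 at an unadjusted p under 0.05, against 2288 with all libraries), 454 without KO 7 and 671 without KO 8.

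In KO cortex 5 of 15 astrocyte, 6 of 12 oligodendrocyte lineage, 8 of 11 meningeal fibroblast and 7 of 16 microglia and macrophage genes rose, while 2, 1, 0 and 1 fell, and 10 of 17 cholesterol synthesis genes fell. None of these 5 lists passed with an estimated correlation (adjusted p = 0.552 for each), a test that few lists can pass with 2 libraries per group. Gfap, the intermediate filament of astrocytes, rose from 20.9 ± 0.697 to 92.8 ± 16.4 FPKM, a ratio of 4.44. Tnc, the matrix glycoprotein tenascin C, rose from 31.8 ± 0.372 to 77.6 ± 7.02 FPKM. Ccbe1, a secreted protein of lymphatic growth, fell from 8.50 ± 0.166 to 2.57 ± 0.331 FPKM. Of 11988 genes tested with limma-trend and BH, 575 were higher and 2124 lower in KO, and 44 of these 2699 had a log2 fold change of at least 1 in size.

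The statistics behind these genes were a log2 fold change of 2.09 (SE 0.11, adjusted p = 1.65e-05) for Gfap, 1.26 (adjusted p = 6.29e-05) for Tnc and −1.42 (adjusted p = 0.000137) for Ccbe1. The nuclear noncoding RNA Malat1 rose from 106 ± 12 to 262 ± 5.77 FPKM (adjusted p = 8.26e-05), Neat1 from 4.69 ± 0.560 to 13.0 ± 2.56 (adjusted p = 0.000879), and the calcium-binding protein gene S100a4 from 3.30 ± 0.256 to 9.14 ± 2.02 (adjusted p = 0.00111). The 3 largest rises were in RNAs whose KO libraries stood far apart. Rn45s, the ribosomal RNA precursor, measured 830.4 FPKM in KO 1 and 3438 in KO 2, against 289.3 and 265.8 in WT. Rmrp, the RNA of a ribonuclease, measured 14.6 and 149.0 against 5.7 and 3.0, and Lars2, a mitochondrial leucyl-tRNA synthetase, 98.5 and 288.5 against 31.8 and 28.3. The log2 fold changes were 2.60, 3.22 and 2.45 for Rn45s, Rmrp and Lars2, whereas the authors' deposited table gave 0.48 (adjusted p = 0.042), 0.24 (adjusted p = 0.213) and 0.62 (adjusted p = 0.0115). Values in that table can be pulled toward 0 where libraries differ, so these sizes are not directly comparable. The call for Rmrp in cortex was lost without WT 2 (log2 fold change 2.86, adjusted p = 0.0758).

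**Figure D3:**
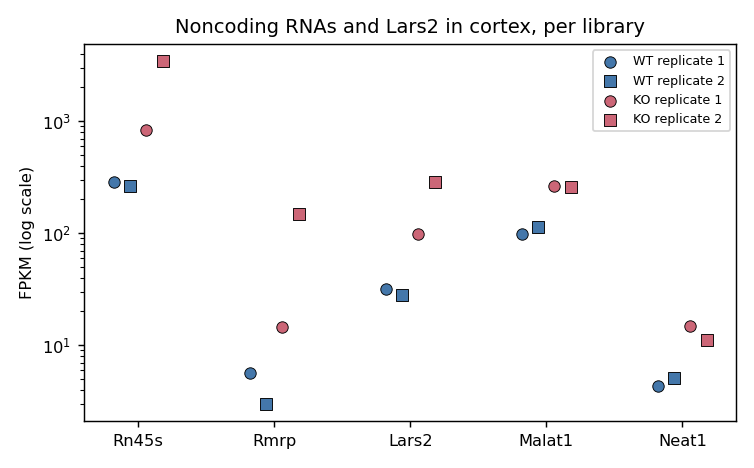
FPKM on a log axis of Rn45s, Rmrp, Lars2, Malat1 and Neat1 in each of the 4 cortex libraries. For Rn45s, Rmrp and Lars2 KO 2 lies above KO 1, whereas for Malat1 (265.9 and 257.7) and Neat1 (14.8 and 11.2) the KO libraries lie close together and above both WT libraries.

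Further falls were in Gpc5, a heparan sulfate proteoglycan, from 4.02 ± 0.276 to 0.932 ± 0.0433 FPKM (adjusted p = 0.000137), and in Rit2, a neuronal small GTPase, from 12.2 ± 0.593 to 4.26 ± 0.463 (adjusted p = 0.000142). The melanocortin receptor gene Mc4r fell by 1.23 on the log2 scale (adjusted p = 3e-04) and the metalloprotease gene Adamts18 fell by 1.15 (adjusted p = 0.000333). The cilium genes Rsph1 and Dynlrb2 had log2 fold changes of −1.28 (adjusted p = 0.00189) and −1.18 (adjusted p = 0.0033). Xlr3b, an X-linked gene with near-identical copies and thus an uncertain value, had −1.21 (adjusted p = 0.00483). Ogfod3, Txnrd2, B3gntl1, Ccdc167, Slc25a26 and Tgoln2 were listed at 0 in both KO libraries. Their WT values were 7.40 and 7.41 FPKM for Ogfod3, 6.39 and 6.39 for Txnrd2, 3.44 and 3.31 for B3gntl1, 3.09 and 3.54 for Ccdc167, 3.39 and 2.97 for Slc25a26, and 2.56 and 1.95 for Tgoln2. The authors' deposited table gave Txnrd2 a log2 fold change of −0.12 (adjusted p = 0.723) and B3gntl1 −0.02 (adjusted p = 0.958).

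Of 15 astrocyte genes 5 rose and 2 fell (5 and 3 adjusted over the list alone, 6 and 0 after rescaling). Besides Gfap these included Id3, from 37.2 ± 1.30 to 77.8 ± 5.10 FPKM (adjusted p = 0.000126), the lipid carrier Apoe, from 208 ± 13.5 to 399 ± 27.0 (adjusted p = 0.000312), and the glycolytic enzyme Aldoc, with a log2 fold change of 0.44 (adjusted p = 0.00302). Of 12 genes of the oligodendrocyte lineage 6 rose and 1 fell (7 and 1 adjusted over the list alone, 7 and 0 after rescaling). Bcas1, a marker of newly formed oligodendrocytes, rose from 2.21 ± 0.0198 to 5.54 ± 0.894 FPKM (adjusted p = 0.00117), and the myelin gene Mbp had a log2 fold change of 0.73 (adjusted p = 0.00641). Of 21 radial glia genes 8 rose and 2 fell (8 and 2 adjusted over the list alone). Besides Tnc, the homeodomain gene Hopx rose to 34.4 ± 5.43 FPKM, a log2 fold change of 1.01 (adjusted p = 0.00111), while the patterning gene Emx2 fell from 5.69 ± 0.274 to 2.67 ± 0.325 (adjusted p = 0.00136). The camera adjusted p values were 0.000253 for astrocytes, 7.13e-06 for the oligodendrocyte lineage and 0.000253 for radial glia, against adjusted p = 0.552 with an estimated correlation for each of the 3.

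Of 11 genes of meningeal fibroblasts 8 rose (9 adjusted over the list alone, 9 after rescaling), among them Col3a1 from 11.2 ± 1.11 to 16.9 ± 0.882 FPKM (adjusted p = 0.00417) and Col1a1 from 6.12 ± 0.188 to 9.25 ± 0.857 (adjusted p = 0.00619). Of 17 extracellular matrix genes 3 rose, also 3 adjusted over the list alone, and 7 after rescaling. These were the brain proteoglycan Ncan from 80.1 ± 0.677 to 152 ± 5.05 FPKM (adjusted p = 0.000126), fibronectin (Fn1, log2 fold change 0.47, adjusted p = 0.00597) and biglycan (Bgn, 0.36, adjusted p = 0.0172). Of 16 genes of microglia and macrophages 7 rose and 1 fell, the same adjusted over the list alone. The lysosomal Cd68 rose from 3.58 ± 0.425 to 7.47 ± 1.51 FPKM (adjusted p = 0.00311) and the complement genes C1qc and C1qa had log2 fold changes of 0.49 (adjusted p = 0.0073) and 0.48 (adjusted p = 0.0192), whereas the purinergic receptor P2ry12 fell from 2.76 ± 0.474 to 1.23 ± 0.140 (adjusted p = 0.0035). Of 12 endothelial and pericyte genes only Vtn rose, by 0.41 (adjusted p = 0.00529), 1 also adjusted over the list alone and 4 after rescaling. The camera adjusted p values of these lists were 1.55e-08, 1.01e-06, 1e-05 and 0.000511, against adjusted p = 0.552 with an estimated correlation for each. Without KO 1, 2 meningeal, 1 matrix and 1 microglial gene rose. Without KO 2 or without WT 2, 3 microglial genes rose, and without WT 2, 5 meningeal genes.

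Of the neuronal lists that follow only the first passed camera. Of 18 pan-neuronal genes 7 rose and 2 fell, the same adjusted over the list alone, and 7 and 1 after rescaling. The neurofilament gene Nefl rose from 48.3 ± 0.00467 to 103 ± 12.9 FPKM (adjusted p = 0.000283) and Nefm by 0.89 on the log2 scale (adjusted p = 0.00292), while the transcription factor Neurod6 fell from 174 ± 0.148 to 132 ± 10.6 FPKM (adjusted p = 0.00702). The camera adjusted p was 0.000153, and adjusted p = 0.552 with an estimated correlation. Of 13 upper layer genes 2 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.266). The netrin receptor Unc5d fell from 4.99 ± 0.0805 to 2.20 ± 0.181 FPKM (adjusted p = 0.00111). Of 16 genes of deep layers and subplate 3 rose and 5 fell, the same adjusted over the list alone, and 4 and 4 after rescaling (camera adjusted p = 0.176). The subplate genes Nr4a2 and Nxph4 rose from 17.8 ± 0.118 to 33.2 ± 1.72 FPKM (adjusted p = 0.000312) and from 2.67 ± 0.473 to 6.53 ± 0.668 (adjusted p = 0.00119), and the deep layer gene Crym fell from 79.3 ± 3.79 to 44.6 ± 5.36 (adjusted p = 0.00111). Of 19 GABAergic interneuron genes 0 rose and 1 fell, the same adjusted over the list alone, and 2 and 1 after rescaling (camera adjusted p = 0.0986).

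Of 17 genes of cholesterol synthesis 10 fell (13 adjusted over the list alone, 5 after rescaling). Idi1, an isomerase of the pathway, fell from 29.8 ± 0.825 to 19.6 ± 1.51 FPKM (adjusted p = 0.00203), and the sterol oxidase Msmo1 from 25 ± 0.779 to 17.1 ± 0.909 (adjusted p = 0.00253). The camera adjusted p was 0.00103, and adjusted p = 0.552 with an estimated correlation. Of 21 genes of synapses and ion channels 4 rose and 8 fell, 4 and 11 adjusted over the list alone, and 4 and 4 after rescaling (camera adjusted p = 0.457). The synaptotagmin Syt4 fell from 99.0 ± 1.48 to 61.4 ± 7.42 FPKM (adjusted p = 0.00157), the sodium channel Scn3a from 12.2 ± 0.0940 to 7.76 ± 0.151 (adjusted p = 0.00203), and the kinase Camk2b rose from 147 ± 4.18 to 208 ± 6.90 (adjusted p = 0.00189). Without KO 1 and without KO 2, 4 and 6 cholesterol genes fell, and 2 and 1 synaptic genes rose with 4 lower in each.

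**Figure D4:**
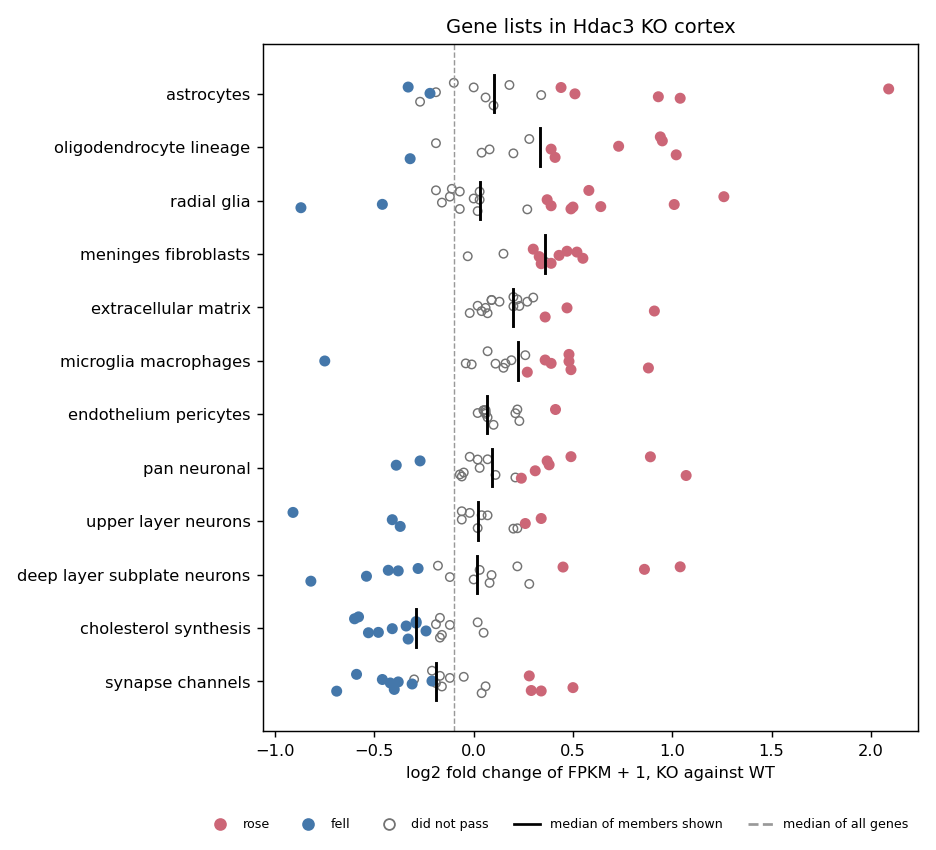
Log2 fold change (KO against WT) of each measured member of 12 gene lists in cortex, with filled points for genes past the limma-trend threshold, a black bar for the median of the members shown and a dashed line for the median of all genes (−0.10). Gfap (2.09) lies farthest to the right, and 10 of 17 cholesterol genes fell.

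Rescaling turned the balance of directions in cortex, whereas in neurospheres it only narrowed it. In cortex the median log2 fold change of all genes was −0.10, and rescaling gave 1131 genes higher and 934 lower. The authors' deposited tables called more genes higher than lower in both tissues, 914 and 799 in cortex and 437 and 288 in neurospheres. The count was 11 with the spread estimated over all 8 libraries. In KO 1 alone, 4 Y-linked genes (Ddx3y, Kdm5d, Eif2s3y and Uty) were listed at 0. By these genes KO 1 was read as female and the other cortex libraries as male, so sex was mixed in KO and not in WT.

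The comparison of tissues asked whether loss of Hdac3 had the same effect in both. For a set of genes it differed: Id1 and Id3 fell in KO neurospheres and rose in KO cortex, the effect on the metallothioneins Mt1 and Mt2 was more negative in neurospheres, and that on collagen IV and Spp1 more positive. Neurospheres and cortex differed in age and culture as well as tissue, and perhaps in driver, and these cannot be told apart here. Of 10947 genes tested in both, the KO effect differed in 153, more positive in neurospheres for 46 and more negative for 107 (limma-trend on all libraries with BH). After rescaling these were 73 and 151. Across genes the log2 fold changes of the tissues had a Pearson r of 0.18 and a Spearman rho of 0.18, where genes are not independent replicates.

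Id3 had a log2 fold change of −1.56 in neurospheres and 1.04 in cortex (difference −2.60, SE 0.20, adjusted p = 0.00328), and Id1 −2.02 and 0.88 (difference −2.90, adjusted p = 0.0139). Hopx had −1.27 (adjusted p = 0.0925) and 1.01, a difference of −2.28 (adjusted p = 0.017). The difference was −3.65 for Mt2 (adjusted p = 0.00645) and −3.02 for Mt1 (adjusted p = 0.0341). It was 3.85 for Spp1 (adjusted p = 0.00863), whose cortex level also rose, from 17.1 ± 0.803 to 37.9 ± 16.1 FPKM. Col4a1 and Col4a2 had differences of 1.96 (adjusted p = 0.00425) and 1.72 (adjusted p = 0.0111), with cortex values that missed the threshold. The test pools the spread of both tissues, so it can understate that of the neurosphere libraries and give p-values that are too small. For Col4a1 the SE of the difference was 0.17, below the 0.19 of its neurosphere change alone, whereas for Col4a2 it was 0.21 against 0.20. Klhl29 (0.79 in neurospheres, −0.78 in cortex) and Dok6 (0.70 and −0.87) had differences of 1.57 (adjusted p = 0.017) and 1.56 (adjusted p = 0.0385), and each fell in cortex only. Klhl29, Dok6, Hopx and Id3 stand in place of B3gntl1, Ccdc167, Taf10 and Cox4i2, which were listed at 0 in KO libraries. The number of genes with a difference ranged from 3 without cortex WT 1 to 1162 without WT 6. It was 4, 6 and 17 without cortex WT 2, KO 1 and KO 2, and 354 and 523 without KO 7 and KO 8.

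**Figure D5:**
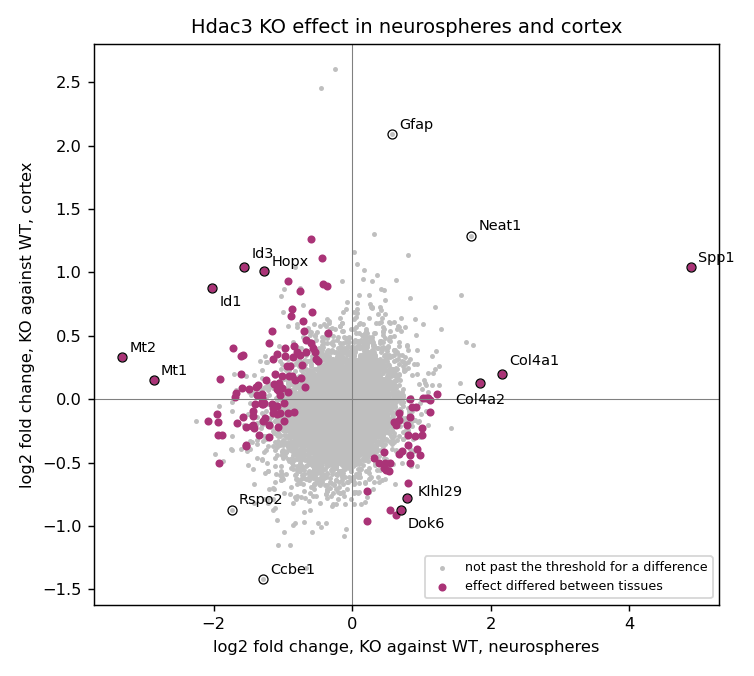
Log2 fold change in neurospheres (x) against cortex (y) for each gene tested in both, with coloured points for the genes whose effect differed and circles for named genes. Id1, Id3 and Hopx lie at the upper left, Mt1 and Mt2 at the far left and Spp1 (4.89, 1.04) at the far right.

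Some genes moved the same way in both tissues. In KO libraries of both tissues 6 genes rose, against 1.19 by chance (one-sided Fisher exact p = 0.000921, BH 0.00368), and 29 fell, against 17.1 (p = 0.00201, BH 0.00402). The genes that rose in both were Neat1 (1.72 in neurospheres, 1.29 in cortex), Spp1 (4.89, 1.04), Rasgef1b (1.57, 0.82), Mbp (1.19, 0.73), Sez6 (1.03, 0.59) and Dcn (1.74, 0.43). Among those that fell in both were Ccbe1 (−1.29, −1.42), the actin regulator Cap2 (−1.14, −0.87), the Wnt agonist Rspo2 (−1.74, −0.87), the thrombin receptor F2r (−1.20, −0.71) and Syt4 (−0.88, −0.69). Plxna2 (0.98, −0.44) and Rph3a (0.84, −0.44) rose in neurospheres and fell in cortex, 2 genes against 4.36 by chance (Fisher exact p = 0.948). Another 6 genes fell in neurospheres and rose in cortex, against 4.66 (Fisher exact p = 0.324): Id1, Id3, Thrsp (−1.16, 0.54), Egr1 (−0.97, 0.40), Rasl11a (−1.72, 0.40) and Cox4i2, which was listed at 0. After rescaling, 20 genes rose in both against 4.96 by chance and 11 fell against 5.16. In the authors' deposited tables, with 12443 genes in both, 162 were higher in both against 29.8 by chance (Fisher exact p = 9.01e-80) and 54 lower against 17 (p = 5.2e-15), while 15 and 18 genes in opposite directions did not exceed chance (p = 0.99 and 0.684). The overlap was 14 genes with a pseudocount of 0.1, 0 without WT 5 or WT 6, where no gene was called in neurospheres, 119 and 135 without KO 7 and KO 8, and 20 and 18 without cortex KO 1 and KO 2.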

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

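Of the tests in this part, those of list shifts between tissues, of library scaling, of a shared rise of other cell types and of fibroblast genes in neurospheres were chosen only after the results were seen.

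The Hdac3 KO effect differed between neurospheres and cortex in 153 genes, by a test of the difference itself (limma-trend on all 8 libraries with BH), which pools the spread of both tissues. Among the named genes the difference, neurospheres minus cortex on the log2 scale, was 3.85 for Spp1, 1.96 for Col4a1, 1.72 for Col4a2, 1.57 for Klhl29 and 1.56 for Dok6. It was −3.65 for Mt2, −3.02 for Mt1, −2.90 for Id1, −2.60 for Id3 and −2.28 for Hopx. With each library left out in turn, 33 of 80 such values for these 10 genes missed the threshold and 0 changed direction, and all but 2 of the 33 (Hopx and Mt1 without neurosphere WT 5) came from leaving out a cortex library.

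Measured as the mean of a list minus that of all other genes, the difference between tissues was 0.97 for GABAergic interneuron genes (camera adjusted p = 8.24e-14), −1.40 for hypoxia genes (adjusted p = 7.37e-13), −0.82 for G2 and M phase genes (adjusted p = 9.46e-11) and −0.79 for astrocyte genes (adjusted p = 7.49e-06). None of these 4 passed with an estimated correlation (adjusted p = 0.266 for each).

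For the interneuron genes in neurospheres the scaling of the libraries is argued against, since the median of the 18 members was 1.17 (SD 0.35) after rescaling. A lower share of progenitors alone would raise the markers of every other type alike. Yet the mean rescaled change was 1.06 for interneuron genes and 0.19 for 64 genes of other neurons and of the oligodendrocyte lineage (difference 0.87, two-sided permutation p = 2e-05 over genes, the smallest the resamples can give). Most of the 64 genes mark cortical neurons or neurons of every kind. A lower share of the whole dorsal lineage need not raise them, so the test cannot decide on it and it stays open. A larger share of interneurons in the KO cultures remains a candidate explanation: all 18 genes were above 0 and 83.3% of them (15) lay within 2 SE of their common mean, from 0.44 for Htr3a to 1.58 for Erbb4. The most abundant named member, Gad1, measured 58.7 ± 7.21 FPKM in WT and 119 ± 4.65 in KO, and it overlaps an antisense transcript. A change in the expression of these genes within the cells of the KO cultures was not tested and stays open.

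In the authors' deposited tables, 70 genes called higher in KO neurospheres and 90 called higher in KO cortex were absent from the FPKM tables used for the comparisons, as were 12 and 79 called lower, so no test of the FPKM values covers them. For the 6 largest of those higher in neurospheres, 5 of them collagens, the authors' deposited table gave log2 fold changes of 4.28 for Col3a1 (adjusted p = 8.27e-74), 3.74 for Col6a3, 3.28 for Col1a1, 3.23 for Col6a2, 2.96 for the cytochrome gene Cyp1b1 and 2.55 for Col6a1.

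The collagens prompted 2 tests in neurospheres, which leave open both a carry-over of every non-neural cell type and fibroblast or meningeal cells in the KO cultures. In the authors' deposited table the mean log2 fold change was 1.04 (SD 1.44) for 11 fibroblast and meningeal genes and 0.08 for 25 endothelial and microglial genes (difference 0.96, two-sided permutation p = 0.00306), and 36.4% of the 11 (4: Col1a1, Col1a2, Col3a1 and Dcn) were higher, between the bounds set. Both tests were first run on members picked by mean count or by having an adjusted p, which gave a difference of 1.03 (SD 1.52, two-sided permutation p = 0.0467) and 66.7% of 6. The demand that the difference exceed the SD was added with the second version, and without it the carry-over would have been excluded in both. Without Col1a1 and Col3a1, which prompted the tests, the values in the authors' deposited table were a difference of 0.35 (SD 0.48, two-sided permutation p = 0.0362) and 22.2% of 9, the latter under the lower bound of 25%. Fold changes in that table can be pulled toward 0 where counts are few, so the mean of endothelial and microglial genes can understate their change.

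In cortex 8 of 11 fibroblast genes rose, and a lower share of the main cell type stays open, since meningeal genes exceeded endothelial, microglial and blood genes by 0.20 (0.44 against 0.25, two-sided permutation p = 0.0227), at the edge of the margin of 0.2 set for the test. A larger share of meningeal tissue in the cortex samples also stays open, since 72.7% of the 11 genes (8) lay within 2 SE of their mean, below the 75% set for the test, from 0.07 for Ogn to 0.66 for Col3a1. A change of these genes within the cells was not tested.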

How the results depend on the processing

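The fits without genes listed at 0, the list tests on the difference between tissues and the list counts without each library were chosen after the data were seen. Of the 62 named results in neurospheres and 75 in cortex, none that passed in the main or the alternative fit changed direction. None of the 10 differences did. Each of the 131 genes called in neurospheres and 2699 in cortex had both KO libraries on one side of both WT libraries. Leaving out a library or changing the pseudocount could therefore not turn their direction, and only rescaling could. For 9 lists in neurospheres and 12 of the 13 described in cortex, the mean minus that of all other genes kept its sign. The median of cortex radial glia went from 0.03 to −0.04 without WT 2 and −0.05 without KO 1. That of cortex deep layers and subplate went from 0.01 to −0.08 without WT 2. The other lists, with that of interneurons in cortex, entered the counts of lists that passed where they had at least 4 measured genes, but their directions were compared only after rescaling. There the median of 7 of them in neurospheres (2 with a single measured gene) and 8 in cortex went from below 0 to above 0, none of them past the camera threshold. The share of changed genes that were higher in cortex went from 21.3% to 54.8% after rescaling and 51.1% after quantile normalization, and in neurospheres from 19.1% to 40% and 44.7%. For each value below that differs from the first one given, the cause was not tested unless stated.

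The count of genes changed in KO neurospheres was 131, and 117 to 159 with other filters, scalings, robust moderation, a fold change minimum or genes at 0 left out. It was 65 with a pseudocount of 0.1, 725 with the authors' deposited adjusted p, and 1668 when the spread was estimated over all 8 libraries. Without each library in turn it ranged from 0 to 671, where the lone library of a group is assumed to vary like the others. In cortex the count of 2699 was 1713 with the authors' deposited adjusted p and 11 with the spread of all 8 libraries, which brings in the neurosphere libraries with their lower correlation between replicates (0.967 and 0.976). A minimum log2 fold change of 1 left 44, by construction. The other settings gave 1924 to 2923, and leaving out libraries 820 to 1895. The replicate numbers 1 and 2 are shared by WT and KO in cortex, and the authors' deposited ratios pair the libraries numbered alike. Whether that pairing reflects a shared litter or batch was not given in the sources used here. The authors' neurosphere ratios also pair libraries in column order, but a replicate block was fitted only in cortex. The deviations of the libraries numbered alike had a correlation of −0.096 across 11988 genes, and with a replicate block 2527 genes changed (559 higher, 1968 lower) and 21 lists passed.

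The number of genes that differed between tissues was 153, then 243 with quantile normalization, 144 to 224 with the other settings and 3 to 1162 without a library. The overlap of 35 genes was 14 with a pseudocount of 0.1, 29 to 38 otherwise, and 0 to 135 without a library. With an estimated correlation 0 lists passed in either tissue (2 in neurospheres and 1 in cortex had an unadjusted camera p under 0.05), against 12 and 19, and without a library 10 to 13 and 17 to 22 passed. Of the 9 neurosphere lists described, S phase (camera adjusted p = 0.221), astrocytes (0.243) and ribosomal proteins (0.221) were lost without KO 7, ribosomal proteins also without KO 8 (0.0607) and extracellular matrix without WT 5 (0.0736), while radial glia was gained without WT 5 (0.0176). Of the same 12 cortex lists none was lost or gained. Of 62 named results in neurospheres, 18 missed the threshold with a pseudocount of 0.1 and 6 after rescaling, where 2 others passed. Of 75 in cortex 0 and 0 did so, and 3 others passed after rescaling. With libraries left out, 89 of 248 neurosphere values and 28 of 300 cortex values missed the threshold, and 9 and 0 newly passed. With 8500000 to 9500000 implied fragments, depth in neurospheres was below that in cortex. On simulated data with independent noise, 87% of log2 changes of 1 in more highly expressed genes were recovered in neurospheres, against 100% in cortex.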

Other observations

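The tests on Rn45s, Rmrp and Lars2 and on the spread of Malat1 and Neat1 between libraries were chosen only after the result was seen, while that on histone genes was set before.

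Single genes of other lists also changed. In KO neurospheres the subplate and deep layer transcription factor Tbr1 rose from 41.6 ± 0.0468 to 75.6 ± 2.70 FPKM (adjusted p = 0.0471), while Ldb2 of the same list fell from 30.5 ± 4.50 to 9.38 ± 0.0269 (adjusted p = 0.0176), 1 higher and 1 lower of 12 (3 and 1 adjusted over the list alone, camera adjusted p = 0.194). The clock and hypoxia gene Bhlhe40 fell from 18.6 ± 1.95 to 6.64 ± 1.10 FPKM (adjusted p = 0.035), 1 of 15 clock genes (1 adjusted over the list alone, camera adjusted p = 0.907). Beyond the lists described with the comparison, camera called 4 more in neurospheres: Cajal-Retzius cells (median 0.35, 0 of 8 genes past limma-trend, also 0 adjusted over the list alone, adjusted p = 0.00166), synapses and channels (0.17, 0 higher and 1 lower of 21, 2 and 2 adjusted over the list alone, adjusted p = 0.0028), fatty acid oxidation (−0.54, 0 of 12, 3 lower adjusted over the list alone, adjusted p = 0.00219) and p53 targets (−0.27, 0 of 19, 5 lower adjusted over the list alone, adjusted p = 0.0209). With an estimated correlation the adjusted p was 0.604 for the first and 0.629 for the other 3.

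In KO cortex the cell cycle inhibitor Cdkn1a rose from 6.16 ± 1.15 to 14.4 ± 2.35 FPKM (adjusted p = 0.00154) and the stress factor Atf5 by 0.75 on the log2 scale (adjusted p = 0.00203). The major histocompatibility genes H2-K1 and H2-D1 rose by 0.59 and 0.47 on the log2 scale (adjusted p = 0.00675 and 0.00359), 3 of 5 genes of that list (4 adjusted over the list alone). The lipid genes Scd2 and Abca1 each rose by 0.59 (adjusted p = 0.00119 and 0.0069), while the semaphorin Sema3c fell from 16.7 ± 0.673 to 7.81 ± 1.83 FPKM (adjusted p = 0.00176). Among the other deacetylases Hdac9 had a log2 fold change of −0.73 (adjusted p = 0.00307) and Hdac5 rose by 0.33 (adjusted p = 0.0102), in a list of 10 with 2 higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.601, median −0.06, or 0.03 after rescaling). Camera called 10 more lists in cortex, and none of them passed with an estimated correlation (adjusted p = 0.724 for the G2 and M phases, 0.609 for oxidative phosphorylation and 0.552 for the others). The camera direction was up for S phase (3 of 16 rose, 0 adjusted over the list alone, camera adjusted p = 0.00083), the Notch pathway (2 of 15, 2 adjusted over the list alone, 0.00103), major histocompatibility class I (0.00029), lipid synthesis (5 of 12 rose and 1 fell, 5 and 2 adjusted over the list alone, 0.00305), fatty acid oxidation (1 of 15, 0 adjusted over the list alone, 0.00502) and the integrated stress response (4 of 10 rose and 1 fell, 5 and 1 adjusted over the list alone, 0.00112). It was also up for the G2 and M phases (0 of 19, 0 adjusted over the list alone, 0.0175), interferon response (1 of 4, 1 adjusted over the list alone, 0.041) and immediate early genes (3 of 5 rose and 1 fell, the same adjusted over the list alone, 0.0101), and down for oxidative phosphorylation (7 of 20 fell, 9 adjusted over the list alone, 0.0214). These last 4 missed the camera threshold after rescaling (adjusted p = 0.084, 0.102, 0.0568 and 0.179), and with an estimated correlation the adjusted p was 0.552 or above for all 10.

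The authors' deposited enrichment tables listed 2001 terms for neurospheres, of which 54 had an adjusted p under 0.05. The lowest was extracellular matrix organization (28 of 230 genes, adjusted p = 5.78e-13), and glycolytic process had 7 of 23 genes (adjusted p = 0.000143). For cortex the authors' deposited table listed 858 terms with 0 under 0.05, the lowest being the neuropeptide signaling pathway (5 of 71 genes, adjusted p = 0.295). Outside the FPKM tables, the authors' deposited table for cortex gave log2 fold changes of 1.5 for Myoc, 1.46 for Col11a2 and 1.32 for the complement gene C4b, and −1.77 for Capn11 and −1.27 for the orexin receptor Hcrtr2.

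Ddx3y measured 10.83 and 10.86 FPKM in cortex WT 1 and WT 2, 8.13 in KO 2 and was listed at 0 in KO 1, and Eif2s3y measured 25.01, 22.03 and 26.09 FPKM in the same 3 libraries and was listed at 0 in KO 1. Kdm5d and Uty were also listed at 0 in KO 1 alone, the pattern of a female animal. In neurospheres 0 of 6 sex-linked genes were measured in the FPKM fit. The authors' deposited table gave mean normalized counts of 27200 for Xist and 409 for Ddx3y there. The FPKM tables had been restricted on both WT libraries, so WT libraries of 1 sex would have kept either Xist or Ddx3y. The absence of both is thus the pattern of WT libraries that differ in sex. Values per library were not at hand for these genes, so the sex of each neurosphere library was not read.

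For Rn45s, Rmrp and Lars2 in KO cortex, KO 2 exceeded KO 1 by 1.54 to 3.26 in log2(FPKM + 1), against a 95th percentile of 0.31 among 574 genes called higher and not listed at 0 in any library. RNA without a poly(A) tail carried over to a different extent in each library stays open for Rn45s and Rmrp, since the 3 were picked for that gap and it cannot test its own cause. Lars2 encodes a protein, so that explanation need not cover it. Why its value moved with the other 2 was not tested. A carry-over that differed between the KO libraries as these 3 did is argued against for Malat1 and Neat1, where KO 2 was not above KO 1 (−0.04 and −0.38). Weaker poly(A) selection in both KO libraries stays open for Malat1 and Neat1: in the authors' deposited table the 8 replication-dependent histone genes with a mean normalized count of at least 10 had a median log2 fold change of 0.20 (SD 0.10), all 8 above 0 and 0 past the authors' threshold, which lies between the bounds set for the test. A rise of Malat1 and Neat1 as an effect of the loss of Hdac3 was not tested apart from the group comparison. In neurospheres the authors' deposited table gave Neat1 a log2 fold change of 1.68 (adjusted p = 9.88e-11), Malat1 0.43 (adjusted p = 0.0675) and Rn45s −0.12 (adjusted p = 0.729).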
